A study of Mus musculus with 2 samples.

How the data were processed

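MicroRNA sequencing (small RNA under 30 nucleotides, per the labels) was done on total RNA of whole thymus from 2 newborn pups of 1 litter, with 1 library per pup. Both libraries form a single group. The deposited tables hold raw read counts per miRNA gene, 1 table per library, not pooled and not normalized. The authors mapped reads to mm10 and counted them over GENCODE annotation M4, per the deposited text files that accompany the tables. The aligner and the counting tool are not given in the sources used here. Each table has 3 count columns without names. From the values, the first equals the sum of the others in every gene, the second holds reads on the strand of the gene, and the third reads on the opposite strand. The second column, which has the larger total, was the main measurement, and the first (unstranded) was an alternative. The tables also give totals for reads that were unmapped (10.6% of replicate 1 and 9.17% of replicate 2), multimapping (56.3% and 57.5%) or outside annotated miRNA genes on both strands (2.99% and 2.57%), and 0 ambiguous reads. These totals were left out of library sizes and tests. Because multimapping reads were tallied apart from gene counts, genes that share their mature sequence with another locus can be undercounted.

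Of 1973 gene identifiers, 1894 matched GENCODE M21, from which symbols, GRCm38 coordinates and overlapping genes were taken. The 79 others had 0 counts on the gene strand. M21 is a later release than M4, so some symbols and boundaries may differ from those used for counting. CPM was the count divided by the library's total on the gene strand. Genes with at least 10 counts in both libraries were called detected and entered tests.

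Scaling used TMM in edgeR 4.0.16 (R 4.3.3). The biological coefficient of variation was the square root of edgeR's common dispersion with an intercept alone, with an interval from 100 bootstrap draws of genes. With 1 group there is no group term to test. Counts of each gene in replicate 2 against replicate 1 were compared by a two-sided exact binomial test given the TMM effective library sizes, with Benjamini-Hochberg adjustment at 0.05 (scipy 1.17.1, Python 3.11.15). Ratios are replicate 2 over replicate 1 with exact 95% intervals. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression, for lists with at least 3 tested members, and read as apart in the outermost 2.5% at either end. The percentiles were not adjusted for the number of lists or of alternatives, so some lists can pass by chance. Intervals of shares are Wilson intervals. PCR reads counted without molecular identifiers are not independent molecules.

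The binomial test was tested on simulated counts with known library sizes. Of 278 simulated genes tested for replicate 2 against replicate 1, it recovered 24 of 28 genes changed 1.5-fold, 27 of 30 changed 2-fold and 24 of 24 changed 4-fold, and called 1 of 196 unchanged genes. These simulated libraries had no spread beyond counting error. The real libraries differ by more than that, so these rates do not carry over to them. Simulated coefficients of variation of 0.05, 0.1, 0.2 and 0.4 over 294 genes were estimated as 0.0503, 0.109, 0.209 and 0.384.

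The 22 gene lists, the comparisons and the rule for naming genes were fixed before the data were examined. The rule takes the 20 genes with the highest mean CPM, the 2 most abundant detected members of each list, and the 4 genes with the largest log2 ratio in each direction among called genes with at least 50 mean CPM. A few further members of the lists are named as examples. The lists covered the miR-181, let-7, miR-15/16, miR-29 and miR-30 families, the miR-17-92 and miR-23/27/24 clusters, the Mir10, Mir99, Mir100 and Mir125 genes, leukocyte, myeloid, erythroid, epithelial, endothelial, mesenchymal, striated muscle, neural, brown fat, and liver, gut and pancreas miRNAs, the pluripotency, Dlk1-Dio3 and X-linked testis clusters, and the H19 and Igf2 genes. Alternatives were the unstranded column, filters of 1 count in either library, 1 count in both or 100 counts in both, DESeq2 1.42.0 size factors, total assigned counts, a pseudocount of 0.5 CPM in place of 1, leaving out the most abundant gene or the genes with numbered copies, a negative binomial test with the common dispersion, and each library alone. Leaving out genes that share 20 bases with another locus, in the lists and the random lists, was added after seeing the data.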

Results

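Small RNA was profiled in the newborn mouse thymus, the organ in which T cells mature among epithelial, mesenchymal and endothelial cells. Both lobes were taken on postnatal day 0 from each of 2 pups of 1 litter of the strain B6NCrl, per the labels, and 1 microRNA (miRNA) library was made per pup. Replicate 1 was pup 2 and replicate 2 was pup 3. Both libraries belonged to 1 group, so the data describe the miRNA content of the tissue and the spread between 2 libraries of littermates. They hold no contrast between conditions. With 1 library per pup, differences between the pups cannot be told apart from those of dissection, library preparation or depth. The labels give both pups the same donor identifier and do not record sex, so that they are separate littermates rests on the descriptions, which name pup 2 and pup 3 of 1 pregnancy. The labels state no further purpose. The count tables covered 10642220 reads in replicate 1 and 4892171 reads in replicate 2, of which 2734133 and 1289151 were counted on the strand of an annotated miRNA gene. Replicate 1 thus had 2.12 times as many assigned counts, and 3 counts, the limit that a count of 0 allows, equalled a level of 1.10 in replicate 1 and 2.33 in replicate 2 in counts per 1000000 assigned counts (CPM). Errors are SD over the 2 libraries (n = 2) unless stated otherwise. Coordinates are those of mouse genome build GRCm38 (mm10).

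Most reads in both libraries mapped to more than 1 place in the genome. These multimapping reads made up 56.3% of replicate 1 (95% Wilson interval 56.285 to 56.345) and 57.5% of replicate 2 (57.459 to 57.546), with a mean of 56.9% ± 0.840. Reads on the strand of miRNA genes made up 26.0% ± 0.467, reads on the opposite strand of these genes 4.40% ± 0.00471, unmapped reads 9.89% ± 1.02, and reads outside the annotated miRNA genes 2.78% ± 0.296. Of the 1973 gene identifiers in the tables, 294 had at least 10 counts in both libraries and were treated as detected, 516 had at least 1 count in both, 191 had at least 100 in both, and 1289 had 0 in both. Multimapping reads were tallied apart from the genes, so reads of a miRNA encoded at several loci with the same sequence can be missing from the counts, and a count of 0 for such a gene is not a limit on the mature miRNA. The reads carry no molecular identifiers described in the labels, so the intervals and floors cover counting error only.

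Counts on the gene strand were led by Mirlet7g, Mir26b and Mir143. Mirlet7g, a member of the let-7 family that accumulates as cells differentiate, had 67816 CPM ± 8810, Mir26b had 59990 ± 8045, and Mir143, a miRNA of smooth muscle and other mesenchymal cells, had 50145 ± 10120. Mir17, the first gene of the miR-17-92 cluster that supports the proliferation and survival of lymphocytes, followed with 45956 CPM ± 2486, then Mir30e with 43148 ± 3468, Mir21a with 40296 ± 1388, and Mir181a-1, a miRNA that raises the sensitivity of the T cell receptor in thymocytes, with 36632 ± 832. Mir126a, a miRNA of endothelial cells, had 32674 CPM ± 6540, Mir93 had 29867 ± 466 and Mir20a had 28814 ± 2851. On the gene strand, the most abundant gene alone took 6.78% ± 0.881 of the counts, the 10 most abundant genes took 43.5% ± 1.17, and the 20 most abundant took 62.2% ± 0.456. The remaining 10 of these 20 ran from Mirlet7i at 24916 CPM ± 3767 and Mir23a at 23564 ± 211 down to Mir322 at 15474 ± 1099, with Mir23b, Mir106b, Mir15a, Mir335, Mir16-1, Mir15b and Mir99a between them. This ranking leaves out the counts on the strand opposite to Mir142b, 387318 and 178605, which exceeded the 202451 and 79394 of Mirlet7g and took 11.98% ± 0.159 of the counts on both strands.

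Most of the leading genes lay within other annotated genes. Mirlet7g (ENSMUSG00000065440.1, chromosome 9, 106178840 to 106178927, plus strand) lay in an intron of Wdr82. Mir26b (ENSMUSG00000065468.1, chromosome 1, 74394310 to 74394394, plus strand) lay in an intron of Ctdsp1, a phosphatase gene. Mir143 (ENSMUSG00000065445.2, chromosome 18, 61649196 to 61649258, minus strand) overlapped no other annotated gene. Mir17 (ENSMUSG00000065508.1, chromosome 14, 115043671 to 115043754, plus strand) lay in an exon of the noncoding host gene Mir17hg. Mir30e (ENSMUSG00000065409.1, chromosome 4, 120772606 to 120772697, minus strand) lay in an intron of Nfyc, Mir21a (ENSMUSG00000065455.1, chromosome 11, 86584067 to 86584158, minus strand) overlapped an exon of Vmp1, and Mir126a (ENSMUSG00000065540.1, chromosome 2, 26591357 to 26591429, plus strand) overlapped an exon of Egfl7, a gene of endothelial cells. Mir181a-1 (ENSMUSG00000065565.1, chromosome 1, 137966455 to 137966541, plus strand) lay in an intron of Gm4258. Of the 20 most abundant genes, 4 (Mir181a-1, Mir23a, Mir23b and Mir16-1) shared a stretch of 20 bases with a miRNA gene at another locus, and their levels are uncertain for that reason.

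**Figure D1:**
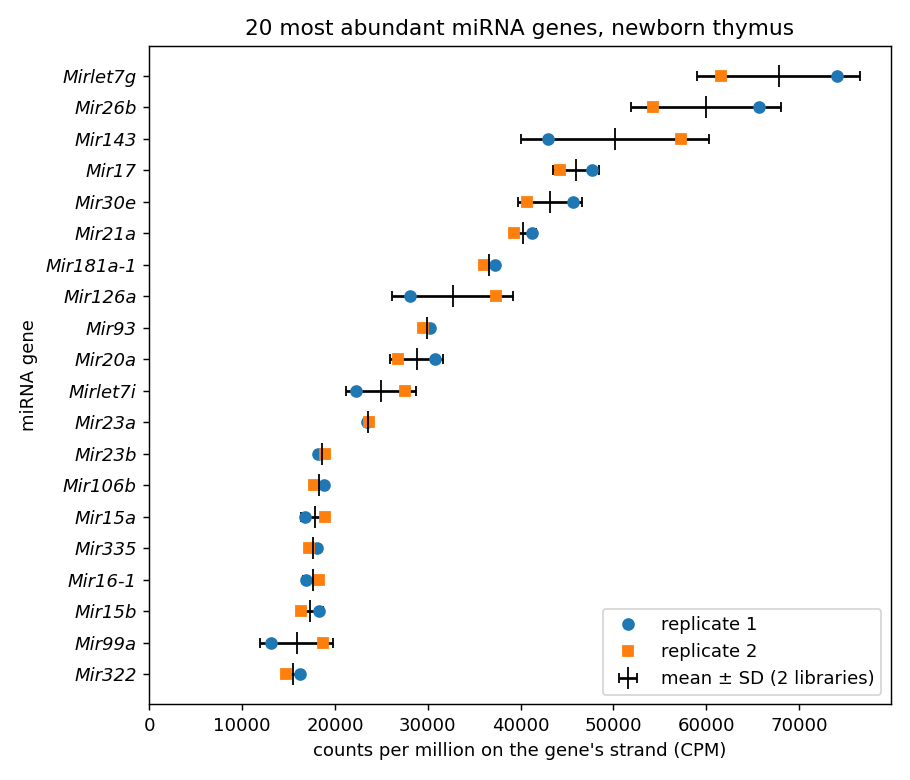
Counts per 1000000 assigned counts (CPM, horizontal axis) of the 20 most abundant miRNA genes (vertical axis), with 1 point per library and the mean ± SD of the 2 libraries in black. Mirlet7g leads at 67816 CPM, and the libraries lie farthest apart for Mir143, with an SD of 10120 CPM.

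Genes of proliferating cells and of differentiation both held large shares. The 15 genes of the miR-17-92 cluster and its paralogs took 17.0% ± 0.700 of all counts and the let-7 family took 11.8% ± 0.664, a ratio of 1.43 ± 0.0211. Within the first list, the cluster from Mir17 to Mir92-1 (chromosome 14, 115043671 to 115044506) took 9.24% ± 0.447, the cluster from Mir106b to Mir25 (chromosome 5, 138165321 to 138165818, in the replication gene Mcm7) took 5.12% ± 0.123, and the cluster from Mir106a to Mir363 (chromosome X, 52741693 to 52742567) took 2.59% ± 0.131. Counts were unequal within the first cluster, with 172 CPM ± 44.0 for Mir19a against 45956 ± 2486 for Mir17, a ratio of 275 ± 56.1. In the let-7 family, Mirlet7g exceeded Mirlet7i by 2.78 ± 0.774 times, and Mirlet7b had 11025 CPM ± 268. Without Mirlet7g in numerator and denominator, the let-7 share was 5.43%. Of the tested let-7 genes, 5 share sequence with another locus and 5 do not, against 4 and 11 in the miR-17-92 list. Mirlet7e and Mirlet7f-1 were not among the counted genes. Multimapping reads were left uncounted, so both shares can be too low, by unknown amounts. The ratio of 1.43 therefore compares counted reads and cannot rank the families by abundance, and its SD does not cover this error.

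The miR-15/16 family, which restrains the cell cycle, took 7.22% ± 0.00134, led by Mir15a with 17873 CPM ± 1534 and Mir16-1 with 17585 ± 981. The miR-30 family took 5.70% ± 0.359, with Mir30d at 10175 CPM ± 101 after Mir30e. The miR-23/27/24 clusters took 4.75% ± 0.116, mostly from Mir23a and from Mir23b at 18560 CPM ± 559. The miR-29 family took 0.341% ± 0.0228, of which Mir29a had 3283 CPM ± 215 and Mir29c 105 ± 10.03. The list of Mir10, Mir99, Mir100 and Mir125 genes took 3.60% ± 0.723, led by Mir99a with 15865 CPM ± 3947 and Mir100 with 10991 ± 2111.

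Among miRNAs of T cells and other leukocytes, the miR-181 family held 6.02% ± 0.389 of the counts, 6.20 ± 0.0997 times the share of the leukocyte and lymphocyte list on the gene strand. Mir181a-1 supplied most of it, followed by Mir181b-2 with 9475 CPM ± 2491, whereas their partners Mir181a-2 and Mir181b-1 had 198 ± 97.7 and 109 ± 33.3. The leukocyte and lymphocyte list took 0.970% ± 0.0471, led by Mir155, a miRNA of activated lymphocytes, with 3513 CPM ± 394 and Mir342 with 3168 ± 147, and with Mir150, a miRNA of mature lymphocytes, at 2093 ± 339. The myeloid list took 0.0871% ± 0.00983, with Mir223, a granulocyte miRNA, at 853 CPM ± 93.2 and Mir511 at 17.6 ± 5.13. The erythroid list took 0.0204% ± 0.00413, with Mir451a at 113 CPM ± 43.8 and Mir144 at 86.2 ± 1.22. Counts over Mir142b lay on the strand opposite to that gene, where Mir142, a miRNA of blood cells, is annotated, so with the unstranded counts the order turned, with the leukocyte list at 12.8% and the miR-181 family at 5.14%. The miR-181 share was 1.53% without genes whose symbol carries a copy number, loci that share sequence.

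Stromal and epithelial miRNAs were also abundant. The smooth muscle and mesenchymal list took 5.32% ± 1.05, with nearly all of its counted reads from Mir143. Mir143 exceeded its neighbour Mir145a (2000 CPM ± 140) by 24.95 ± 3.31 times. Mir126a, the counted member of the endothelial list, took 3.27% ± 0.654. The epithelial list took 4.01% ± 0.0696, with Mir205, a miRNA of stratified and thymic epithelium, at 9875 CPM ± 749, Mir429 at 9335 ± 730 and Mir200c at 9304 ± 1550. The mesenchymal share exceeded the epithelial share by 1.32 ± 0.240 times. The epithelial share exceeded the myeloid share by 46.4 ± 6.04 times. In the mesenchymal list, Mir199a-1 (1.87 CPM), Mir199a-2 (11.1) and Mir199b (62.2) share 20 bases with other loci, whereas the 7 epithelial genes share none. The mesenchymal share can thus be too low, by an unknown amount. The ratio of 1.32 compares counted reads only, and its SD does not cover this error. No test was run between the shares of these lists, which are given as values.

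Lists of other tissues, the Dlk1-Dio3 cluster, the H19 and Igf2 genes and the pluripotency clusters held small shares. The liver, gut and pancreas list took 0.705% ± 0.00908, nearly all from Mir375, a miRNA of endocrine and some epithelial cells, at 6561 CPM ± 165, followed by Mir192 at 227 ± 50.4. The Dlk1-Dio3 imprinted cluster of chromosome 12 took 1.28% ± 0.241, led by Mir411 at 2290 CPM ± 902 and Mir127 at 2263 ± 373. The striated muscle list took 0.0619% ± 0.0180, with Mir206, a skeletal muscle miRNA, at 444 CPM ± 2.09 and Mir208b at 103 ± 115. The brown fat list took 0.0514% ± 0.00165 (Mir455 at 503 CPM ± 20.7 and Mir193b at 11.8 ± 4.21), the X-linked testis cluster 0.0275% ± 0.000458 (Mir224 at 244 ± 6.63 and Mir452 at 23.5 ± 0.355) and the H19 and Igf2 genes 0.0192% ± 0.00607 (Mir483 at 163 ± 53.1 and Mir675 at 29.5 ± 7.61). Nearly all counts of the X-linked testis list came from Mir224 and Mir452, which lay in an intron of Gabre. Its other members had at most 5 counts in either library, so the share says little about them. The neural list took 0.0152% ± 0.00212 (Mir137 at 71.4 CPM ± 18.7 and Mir219a-1 at 40.7 ± 0.443), and the pluripotency clusters took 0.00777% ± 0.000535 (Mir294 at 18.2 ± 1.64 and Mir293 at 16.9 ± 3.03). Mir124a-1, Mir124a-2 and Mir124a-3, the loci of a neuronal miRNA, had 0 counts in both libraries, but they share sequence with each other and their reads are not counted when multimapping.

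**Figure D2:**
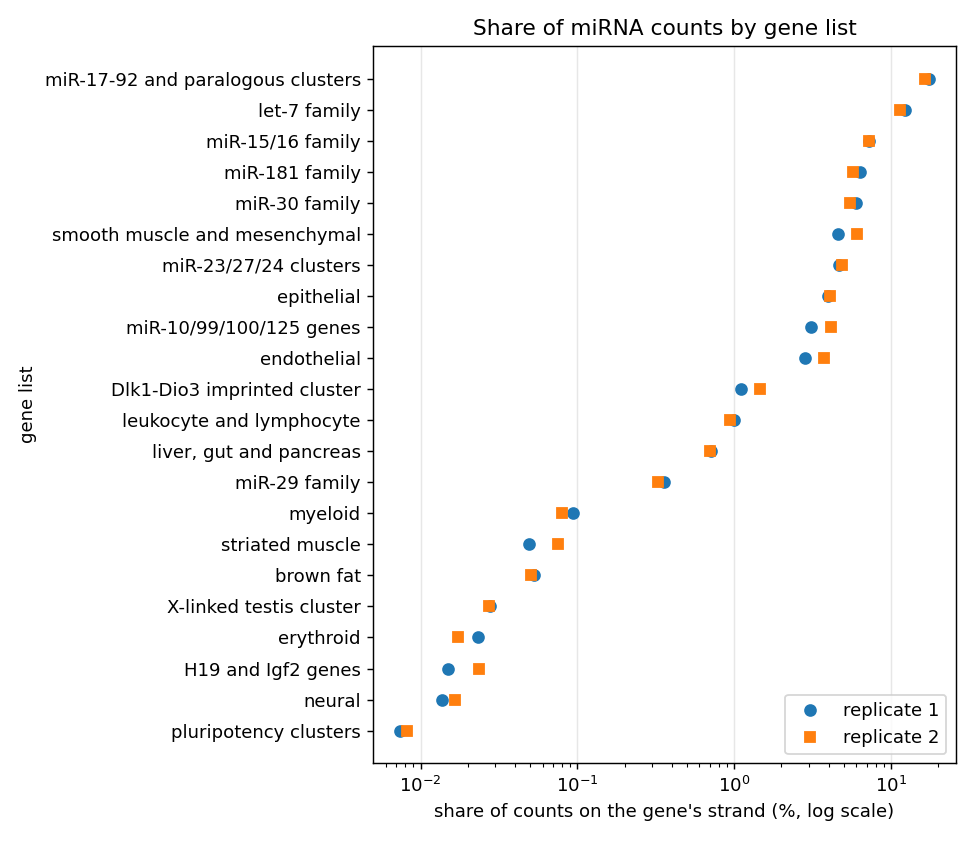
Share of the counts on the strand of miRNA genes (percent, log scale, horizontal axis) taken by each of the 22 gene lists (vertical axis), with 1 point per library. The shares run from 17.0% for miR-17-92 and its paralogs to 0.00777% for the pluripotency clusters, and among lists the libraries lie far apart for the H19 and Igf2 genes (0.0149% and 0.0235%) and for striated muscle (0.0492% and 0.0747%).

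The littermates had closely similar profiles. Of the 294 detected genes, 288 differed by less than 2-fold between the libraries and 243 by less than 0.5 on the log2 scale, and the median absolute log2 ratio was 0.21. Across these genes, which are not independent replicates, log2(CPM + 1) had a Pearson r of 0.994 and a Spearman rho of 0.992. The biological coefficient of variation, the spread between libraries beyond counting error, was 0.154 (bootstrap interval over genes 0.124 to 0.197). The interval does not cover variation over pups. The counts nevertheless differed by far more than sampling noise (chi-square 27452 on 683 degrees of freedom), so the files are not copies of the same library.

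Among called genes with a mean of at least 50 CPM, those farthest apart between the littermates were Mir208b, Mir181a-2 and genes of the Dlk1-Dio3 cluster, which were higher in replicate 2, and Mir451a and 3 genes with numbered copies, which were lower. Mir208b (ENSMUSG00000077928.1, chromosome 14, 54975700 to 54975776, minus strand), in an intron of the cardiac myosin gene Myh7, had 60 counts in replicate 1 and 238 in replicate 2, a log2 ratio of replicate 2 over replicate 1 of 3.01 (exact 95% interval 2.59 to 3.44, adjusted exact binomial p = 1.2e-60). Mir181a-2 (log2 ratio 0.99), Mir411 (0.76) and Mir543 (0.65) were the next highest in replicate 2. Mir451a, a miRNA of red blood cells, had a log2 ratio of -0.88 (-1.20 to -0.56), followed by Mirlet7a-1 (-0.74), Mir103-2 (-0.72) and Mir181b-1 (-0.70). Among abundant genes, Mir143 (log2 ratio 0.35), Mir126a (0.34) and Mir99a (0.45) were higher in replicate 2, and Mirlet7g (-0.33), Mir26b (-0.34) and Mir181b-2 (-0.61) were lower. Exact binomial tests with Benjamini-Hochberg adjustment called 128 of 294 genes, 59 higher and 69 lower in replicate 2, and 142 passed at an unadjusted p under 0.05. Scaled to total assigned counts, the split was 72 higher and 52 lower. These tests compare the 2 libraries by counting error, and the counts of Mir181a-2, Mir181b-1, Mir181b-2, Mirlet7a-1, Mir103-2 and Mir411 are uncertain because other loci share 20 bases with them. A negative binomial test in edgeR called 1 gene, Mir208b, and passed 15 unadjusted, but it sets 1 library against 1 with a spread estimated from the same libraries, so the differences have no replicate check.

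Among the gene lists, 8 of 10 tested let-7 genes were lower in replicate 2, and 11 of 37 tested Dlk1-Dio3 genes and 2 of 3 tested striated muscle genes were higher. Of the other let-7 genes, 1 was higher (Mirlet7i, log2 ratio 0.24) and 1 did not pass, with 9 lower and 1 higher when adjusted over the list alone. Mirlet7e and Mirlet7f-1, whose loci have counts on the strand opposite to Gm25927 and Gm24111, were not among the 10, and those counts had log2 ratios of -0.07 (exact 95% interval -0.16 to 0.0083) and 0.0044 (-0.28 to 0.29). The let-7 median of -0.28 lay at the 0.24 percentile of 10000 random lists matched on expression, but this depended on genes with shared sequence. The 5 tested let-7 genes that share 20 bases with another locus, whose counts are uncertain, had a median of -0.43, and the 5 others had a median of -0.18 at the 19.1 percentile among genes that share none, an alternative chosen after seeing the data. Of the 37 tested Dlk1-Dio3 genes, 30 had a ratio above 0, 11 were higher and none lower, also when adjusted over the list alone, and 26 did not pass. The Dlk1-Dio3 median was 0.27, at the 99.9 percentile. It was 0.17 at the 97.1 percentile with at least 100 counts required in both libraries, and there it no longer passed, and 0.28 at the 98.96 percentile over the 34 genes that share no sequence. Random lists drew their genes 1 by 1, whereas the genes of this cluster lie close together and may shift together. Its percentile can thus overstate how unusual the cluster is. Counts on the opposite strand of other genes, where the cluster members Mir299a, Mir409, Mir376a and Mir380 are annotated, had log2 ratios of 0.34, 0.12, 0.04 and -0.10 and were not in this test. Beside Mir411, this cluster held Mir431 (log2 ratio 0.55), Mir369 (0.64) and Mir127 (0.27). Of the 3 tested striated muscle genes, Mir208b and Mir499 (log2 ratio 1.48, 32 and 44 counts) were higher and Mir206 did not pass (-0.08), with a median of 1.48 at the 99.98 percentile, or 0.68 at the 99.8 percentile over genes with at least 1 count in either library. Members with too few counts to be tested, named after their values were seen, went both ways: Mir208a 5.15, Mir133b -1.23 and Mir1b -1.44.

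The remaining lists with at least 3 tested members stayed outside the outermost 2.5% of random lists at either end. The miR-181 family had a median of -0.25 (percentile 3.18), with 1 gene higher and 4 lower, and the leukocyte and lymphocyte list had a median of -0.23 (percentile 3.04), with 1 higher and 3 lower. The leukocyte median was -0.15 (percentile 10.7) with the unstranded counts and 0.03 (percentile 63.6) with at least 1 count in either library, so its direction depends on the filter. The smooth muscle and mesenchymal median was 0.26 (percentile 92.5), with Mir143 and Mir214 (log2 ratio 0.51) higher, and the epithelial median was 0.05 (percentile 81.0), with 3 genes higher and 2 lower, or 5 higher and 2 lower when scaled to total assigned counts. The miR-17-92 list had a median of -0.12 (percentile 13.7), with 2 genes higher and 11 lower, or 2 higher and 7 lower when scaled to total assigned counts. The percentiles were 49.2 for the miR-15/16 family, 9.22 for miR-29, 25.1 for miR-30, 72.6 for miR-23/27/24, 81.6 for the Mir10, Mir99, Mir100 and Mir125 genes, 30.3 for neural genes, 55.0 for liver, gut and pancreas, and 17.9 for the pluripotency clusters. The direction also turned for 3 of these with at least 1 count in either library, to a median of 0.46 (percentile 90.4) for neural genes, -0.14 (percentile 23.4) for liver, gut and pancreas, and 0.51 (percentile 91.0) for the pluripotency clusters. Without genes that share sequence, an alternative chosen after seeing the data, 2 of the lists passed. The mesenchymal median was then 0.35 (percentile 98.1) over 3 genes, which include the neighbours Mir143 and Mir145a. The median of the Mir10, Mir99, Mir100 and Mir125 genes was 0.22 (percentile 98.06) over 6 genes. Percentiles describe these 2 libraries and are not a test of any condition. They treat genes as independent, so for lists that hold neighbouring genes they can be too extreme. They were also not adjusted for the number of lists.

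**Figure D3:**
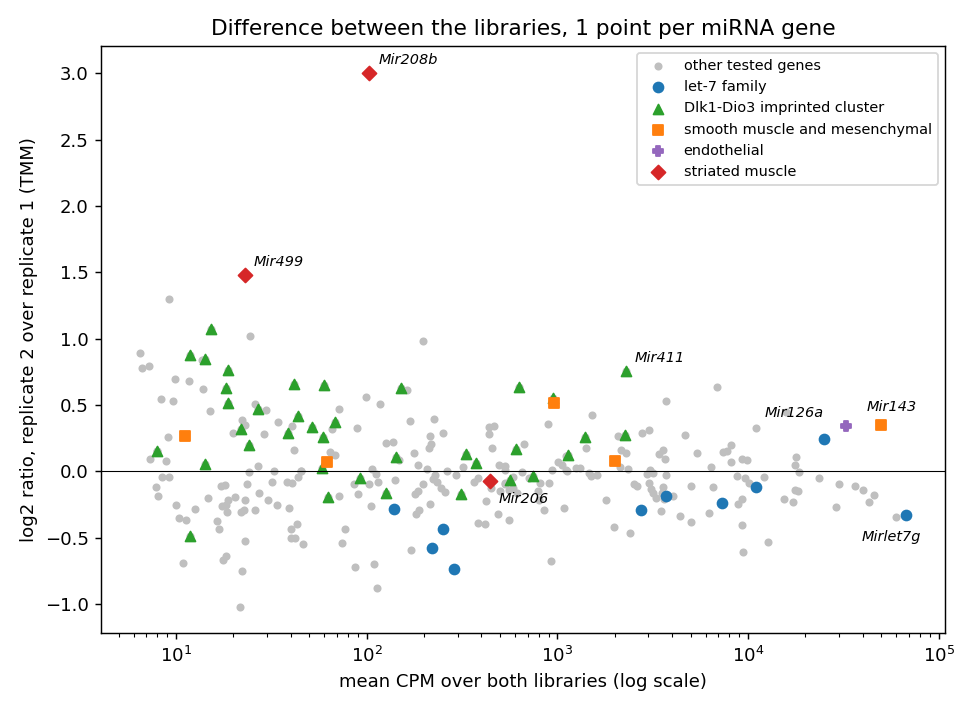
Log2 ratio of replicate 2 over replicate 1 after TMM scaling (vertical axis) against mean CPM (log scale, horizontal axis) for the 294 detected miRNA genes, 1 point per gene, with 5 gene lists in colour. Mir208b lies highest at 3.01, and the tested let-7 genes lie below 0 except Mirlet7i at 0.24.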

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

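Of the tests in this part, the one of strand loss over the whole library was chosen after the result was seen. Outside the main measurement, 10 genes had more counts on the opposite strand than on their own in both libraries, above the limit of 3 counts that a count of 0 allows. Mir142b had 387318 such counts in replicate 1 and 178605 in replicate 2, which was 11.98% ± 0.159 (SD, n = 2) of all gene counts on both strands. In replicate 1, Gm25301 had 37133, Gm24083 had 32754, Gm25927 had 3696, Gm25252 had 2630, Gm24321 had 1674, Mir299b had 1030, Mir497b had 836, Gm25750 had 787 and Gm24111 had 313. These 10 genes held 99.96% of the opposite-strand counts of replicate 1 and 99.93% of those of replicate 2.

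A loss of strand over the whole library would put counts on the wrong strand of every abundant gene, but the median share on the opposite strand was 0% over 201 genes with at least 100 counts in both libraries. The candidate explanation is a miRNA gene on the other strand that the counting annotation lacks. All 10 genes overlap a differently named RefSeq miRNA, against 27 of 1884 other genes (1.43%), and in GENCODE M21 the miRNAs on their opposite strand are Mir142, Mir378a, Mir191, Mirlet7e, Mir376a, Mir409, Mir299a, Mir497, Mir380 and Mirlet7f-1. Looked up by M21 identifier, 0 of these 10 miRNAs were among the counted genes, as the explanation requires. The M4 annotation itself was not looked up. If the opposite-strand reads are theirs, Mir142 may be the most abundant miRNA of these libraries, since its 387318 reads in replicate 1 exceed the 202451 of Mirlet7g, and the leukocyte share is 12.8% with the unstranded counts. No biological explanation was tested for these counts.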

How the results depend on the processing

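All alternatives were planned except that leaving out genes that share 20 bases with another locus was chosen after seeing the data. Of the shares, counts and tests that describe whole libraries or lists, 168 alternative values stayed within the spread or on their side of the threshold, 46 moved, 4 became weaker, 3 stronger and 4 reversed. The reversed ones were list medians that passed in neither setting, with at least 1 count in either library: leukocyte 0.034, neural 0.46, liver, gut and pancreas -0.14 and pluripotency 0.51. Without genes sharing 20 bases, the let-7 median was -0.18 and no longer passed, and the mesenchymal median of 0.35 and that of the Mir10, Mir99, Mir100 and Mir125 genes of 0.22 now passed; the miR-181, miR-29, miR-23/27/24 and neural lists had too few genes left. Detected genes numbered 516 with 1 count and 191 with 100 counts in both libraries, the replicate correlation was 0.987 with 1 count in either library, and the Dlk1-Dio3 median was 0.17 with 100 counts in both. The negative binomial test, which adds a spread estimated from the same 2 libraries, called 1 gene. With the unstranded column, 30.4% of reads were assigned, the top 10 genes took 46.7%, the leukocyte list 12.8% because it gained the counts over Mir142b, and other lists shrank with the larger denominator: miR-17-92 14.5%, let-7 10.1%, miR-15/16 6.20%, miR-181 5.14%, miR-30 4.87%, miR-23/27/24 4.06%, epithelial 3.43%, liver, gut and pancreas 0.603%, miR-29 0.292%, myeloid 0.0745%, brown fat 0.0440%, X-linked testis 0.0235% and pluripotency 0.00664%. With changed denominators, without Mirlet7g the top 10 took 42.1%, let-7 5.43%, miR-17-92 18.2%, miR-15/16 7.74%, miR-181 6.45%, miR-30 6.12%, miR-23/27/24 5.10%, epithelial 4.31%, leukocyte 1.04%, liver, gut and pancreas 0.756%, miR-29 0.366%, brown fat 0.0552%, X-linked testis 0.0295% and pluripotency 0.00833%. Without numbered copies the top 10 took 47.1%, miR-17-92 17.7%, let-7 12.8%, miR-30 6.32%, miR-15/16 5.71%, miR-23/27/24 5.23%, epithelial 4.46%, miR-181 1.53%, leukocyte 1.08%, liver, gut and pancreas 0.769%, miR-29 0.377%, brown fat 0.0572%, X-linked testis 0.0305%, neural 0.0115% and pluripotency 0.00863%. Either library alone stayed within 1 SD of each mean share, which holds by construction with 2 libraries. The 168 values that stayed include 22 such list shares for each library, which are no evidence of stability. Of values for single genes, 146 stayed, but these include 47 CPM values for each library alone, which also hold by construction. With the unstranded column 33 CPM values moved, and 7 of 8 named log2 ratios were no longer called by the negative binomial test. No paired analysis was possible because there is 1 group. Replicate 2 has fewer counts, so genes near 10 counts are limited by its depth.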

Other observations

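Several abundant miRNA genes lay outside the lists. The list members together took 72.3% ± 0.679 (SD, n = 2) of the counts, and the 10 most abundant genes outside them took 18.0% ± 0.781. After Mir26b, Mir21a and Mir335 these were Mir128-1 with 12775 CPM ± 2913, Mir130b with 12196 ± 158, Mir140, a cartilage miRNA, with 8128 ± 550, Mir22 with 8120 ± 1064, Mir130a with 7365 ± 758, Mir423 with 6886 ± 2322 and Mir652 with 6432 ± 306. Mir128-1 was lower in replicate 2 (log2 ratio -0.54, exact 95% interval -0.56 to -0.51) and Mir423 was higher (0.64, interval 0.60 to 0.67). These genes were chosen by abundance after the lists were set aside.

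Further genes outside the lists were also picked after their abundance was seen. Mir182 had 4032 CPM ± 242 and Mir449a had 3574 ± 83.9. On chromosome 2, members of the rodent Mir467 family had similar levels, with 3580 CPM ± 400 for Mir467c, 2955 ± 70.9 for Mir467e and 2773 ± 485 for Mir467d, but they share 20 bases with 16, 16 and 14 other loci and their levels are uncertain.

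Of the tests below, those of heart, skeletal muscle, thymocyte share and gene copies were chosen after the results were seen, and that of neighbouring genes before; those of heart and thymocyte share replaced earlier tests, the first of which rested on the lower bound of 0.79 for Mir499, a gene that raised the question. Mir208a, from an intron of the cardiac myosin gene Myh6 and named here after its values were seen, had 6 counts in replicate 1 and 105 in replicate 2, 35.4-fold higher after scaling (exact 95% interval 15.8 to 98.8), beside 8.03-fold for Mir208b and 2.79-fold for Mir499. More skeletal muscle in replicate 2 is argued against by Mir206, whose upper bound on the log2 ratio was 0.0687. Whether heart tissue was carried over with the lobes stays open. Mir1b and Mir133b, muscle miRNAs of the list that did not raise the question, had 30 counts in replicate 1 and 6 in replicate 2. Their log2 ratio was -1.30 (exact 95% interval -2.86 to -0.02). It cannot decide, because the 6 counts of replicate 2 are under the 10 that this test required in both libraries. The list also does not separate heart miRNAs from those of skeletal muscle. Mir1b and Mir133b share sequence with other loci, as do Mir1a-1, Mir133a-1 and Mir133a-2 at 0 in both. A lower share of thymocytes could raise Mir143 and Mir126a and would raise epithelial miRNAs alike. The median log2 ratio was 0.05 for 7 epithelial genes and 0.30 for 6 mesenchymal and endothelial genes, a difference at the 9.53 percentile of 10000 random pairs of lists matched on expression, which leaves this open as well. Lists of T cell and leukocyte miRNAs were not part of this test. The miR-181 median was -0.25 (percentile 3.18), with 1 gene higher and 4 lower in replicate 2. The leukocyte median was -0.23 (percentile 3.04), with 1 higher (Mir150, 0.27) and 3 lower. Neither list lay in the outermost 2.5%. The counts on the strand opposite to Mir142b had a log2 ratio of -0.10.

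Genes that share sequence with other loci tended to have low counts. Among 197 list members, the 62 that share 20 bases with another miRNA locus had a median of 22.6 CPM and the 135 others 127 CPM, a ratio of 0.178, and 13 and 10 of them were at 0 in both libraries. Reads shared between copies and left uncounted may be a cause. Multimapping reads outnumber counted ones, but how many of them come from miRNA genes is not known. This cause cannot be told apart from lower expression of these genes, because multimapping reads are not divided among loci. In addition, 4 of the sharing genes exceeded 10000 CPM.

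A further hypothesis was that neighbouring miRNA genes deviate together between the pups because they share a primary transcript. Over 104 pairs of detected neighbours on 1 strand within 10000 bases, the mean absolute difference of log2 ratios was 0.33, against 0.42 for shuffled genes (one-sided permutation p = 0.00618, 100000 shuffles across genes, which are not independent replicates). Without the Dlk1-Dio3 cluster, 69 pairs gave a permutation p of 0.0117. The result goes with the hypothesis, but shuffling did not match genes on counts. Mir181a-2 and Mir181b-2, which lie side by side, went opposite ways (0.99 and -0.61). Both share 20 bases with another locus, so their counts are uncertain and this pair does not decide the question.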
